A study of Mus musculus with 2 samples.

How the data were processed

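H3K4me3 was measured by ChIP-seq in limb tissue of mouse embryos at 13.5 days, in 2 biological replicates of 1 group. The replicate numbers were taken from the labels, which name separate tissue samples. There was no other group, so no test between groups was made.

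Per the file headers, which here are text files describing each deposited file, all peak lists were made on the mm10 build. The peaks of each replicate were derived from that replicate's alignments with a control file, and pooled peaks from the alignments and controls of both. The replicated peaks were derived from the pooled list and both replicate lists. The peak caller, its version, the rule for calling a peak replicated, the aligner and the filters on reads are not given in the sources used here. The fold of a peak is the authors' signal value in the narrowPeak layout, taken as a ratio over the control from its range of 1.21 to 86.1 in the pooled list, since no source states its meaning. The score of a peak, as deposited, is a display value and was not used. The deposited −log10 p and −log10 q are the authors' values for each peak. The smallest −log10 p was 2.05, 2.09 and 2.01 in the replicate 1, replicate 2 and pooled lists, so weak peaks were kept by the authors, and −log10 q of at least 2 was tried as a stricter limit. Read counts were not analysed here, so the depth per replicate is unknown. A deeper library gives more and wider peaks, which acts on counts and breadths. Breadths were averaged over the replicates and compared between them as ratios with no correction for depth.

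Peak ends were checked to lie within the chromosome lengths of GRCm38, the reference used, whose sequence is that of mm10. Gene annotation was GENCODE M21. Chromosomes 1 to 19, X and Y were analysed. Overlaps needed at least 1 bp. Random placement moved each peak within its own chromosome 20 times. Intervals for shares are exact binomial 95% intervals, which cover counting only. A promoter was the window of 1000 bp on either side of the start site of any protein-coding transcript, and a gene was marked when a replicated peak overlapped one. A peak was assigned to the first that applied of protein-coding promoter, start site of another annotated gene, exon, intron and intergenic.

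A domain joined the peaks of a replicate that overlapped a replicated peak and were separated by at most 500 bp. Breadth was the span of the widest domain touching a gene's promoter window, averaged over the 2 replicates, for genes with a domain in both. Neighbouring genes can share a domain and then have the same value. Covered bases, an alternative measure, were counted for every gene with such a peak within 5000 bp of a start site in both replicates, so some lists then held more genes. CpG dinucleotides were counted within 500 bp on either side of a start site, with the highest count of a gene used, and genes were put in 10 groups of equal size.

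The 24 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes, except where a choice is said to follow the data. There were 9 lists of limb lineages, 6 of other cell types in the limb, 7 of other tissues and 2 of ubiquitous genes. All symbols but Ahsp of the erythroid list matched the annotation. Presence by list was tested with Fisher's exact test, two-sided, against all other protein-coding genes, and again with an exact test within CpG groups. Breadth was tested with a two-sided permutation test of the list median against 100000 random lists of the same size, for lists with at least 3 genes with a domain. The broadest 5% were tested with Fisher's exact test. Posterior HoxA and HoxD genes were compared with posterior HoxB and HoxC genes by an exact permutation test of the mean. The p values were adjusted over the lists by the Benjamini-Hochberg method at a threshold of 0.05. Genes are not independent replicates, and these tests describe lists of genes in this tissue rather than a difference between animals.

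The genes named are the 25 broadest domains, with genes of a shared domain counted as 1. From each list the 2 broadest members and the first 2 in alphabetical order without a replicated promoter peak are named. Any member of a list of up to 10 genes could be named, and not all of them are. A fixed set of limb genes was always named (Tbx5, Tbx4, Pitx1, Shh, Gli3, Hand2, Grem1, Fgf8, Fgf10, Lmx1b, En1, Wnt7a, Hoxa13, Hoxd13, Sox9, Gdf5, Myod1 and Scx), with the other Hox genes as a group. The rest are the 5 genes at each end of the replicate ratio among those with a domain of at least 1000 bp in a replicate. Klf1, Gypa, Nfe2, Apoa1, Proc, Tdrd1 and Olfr1033 were named to complete a short count, chosen after their values were seen.

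The alternatives were windows of 500 and 2000 bp, the 5′ end of the gene as the single start site, overlaps of 50%, stricter peaks, the pooled list, gaps of 0 and 1000 bp, covered bases within 5000 bp, the broadest 10%, genes matched on CpG content, and each replicate left out. Chosen after seeing the data were 1 gene per domain, domains that touch a single gene, and covered bases for the Hox comparison. Peaks on unplaced contigs were left out of all comparisons.

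The steps were tested on simulated data. The overlap and breadth functions returned the planted answer for 500 of 500 items each. Of 200 simulated lists of 20 genes with no effect, 2% were called by the presence test (21826 genes) and 3.5% by the breadth test (14597 genes). Of 200 lists with 97% of members marked, 98% were called, and of 200 lists made 1.5-fold broader, 79% were called. A call in these simulations was an unadjusted p under 0.05. Marks and breadths were drawn for each gene separately, without regard to CpG content or shared domains. The rates therefore do not describe adjusted calls or shorter lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.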

Results

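H3K4me3, the trimethylated form of lysine 4 of histone H3 found at active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in limb tissue of mouse embryos at 13.5 days of gestation. At this age the digits are separating and cartilage, joints, tendon and muscle are being laid down. The tissue came from strain B6NCrl embryos of both sexes, pooled. There was 1 group of 2 biological replicates, so the comparisons lie between the replicates, between regions of the genome and between groups of genes within this tissue. The labels name separate tissue preparations for the replicates.

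The data were peak lists on the mm10 genome. Replicate 1 had 32920 peaks covering 42.6 Mb and replicate 2 had 31142 peaks covering 40.5 Mb. The pooled list, made from both replicates together, had 33788 peaks covering 45.2 Mb, and the replicated list had 25855 peaks covering 43.1 Mb. The sequencing depth behind these lists is unknown, since they hold no read counts, and intervals given here cover the counting of peaks or genes only. Fold enrichment is the authors' value for each peak and was used to describe or rank peaks within a list.

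The same H3K4me3 regions were called in both replicates over most of the marked sequence. Of the replicate 1 peaks on chromosomes 1 to 19, X and Y, 26329 of 32908 (80%, exact 95% interval 79.6 to 80.4) overlapped a replicate 2 peak, and 27104 of 31130 replicate 2 peaks (87.1%, interval 86.7 to 87.4) overlapped a replicate 1 peak. After random placement on the same chromosomes the shares were 2.97% ± 0.0716 and 3.09% ± 0.115 (SD, n = 20 placements). The replicates shared 37.4 Mb, which was 88.0% of the replicate 1 bases and 92.5% of the replicate 2 bases. Peaks found in 1 replicate alone were narrow and weak. Their median width was 235 bp in replicate 1 and 227 bp in replicate 2, against 1294 and 1192 bp for shared peaks, and their median fold enrichment was 2.93 and 2.94, against 21 and 18.7. They held 4.16% of the covered bases of replicate 1 and 2.55% of those of replicate 2. Across 26329 overlapping pairs, the rank correlation of fold enrichment was 0.877 (Spearman's rho). This is a correlation across regions, which are not independent replicates.

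The replicated list held the strong and wide peaks of the pooled list. It kept 25855 of the 33788 pooled peaks (76.5%), each with an identical entry in the pooled list. With pooled peaks ranked by fold enrichment and divided into 4 groups of about equal size, 17.3% of the lowest group were kept, 89.7% of the second and 100% of the upper 2. Kept peaks had a median width of 1411 bp and a median fold enrichment of 24.7, and peaks that were not kept had medians of 227 bp and 2.64. Of the kept peaks, 1123 did not overlap a peak in both replicate lists, with 728 overlapping replicate 1 alone, 372 replicate 2 alone and 23 neither.

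Promoters of protein-coding genes held most of the replicated H3K4me3. Of 25844 replicated peaks on the main chromosomes, 14966 (57.9%) overlapped the window of 1000 bp on either side of a protein-coding transcription start site, against 4.49% ± 0.113 after random placement (SD, n = 20 placements). These promoter peaks held 79.4% of the covered bases, with a median width of 2130.5 bp and a median fold enrichment of 51.8. Another 5.54% lay at the start site of another kind of annotated gene (3.80% after random placement), 7.18% in exons (9.26%), 11.5% in introns (27.3%) and 17.8% between genes (55.2%). Intronic peaks had a median width of 510 bp and a median fold enrichment of 4.02, and intergenic peaks 637 bp and 5.83. The promoter share was 49.0% in the replicate 1 list and 51.3% in the replicate 2 list, which hold more of the narrow, weak peaks.

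About 2 of every 3 protein-coding genes carried the mark at a promoter. A gene was counted as marked when a replicated peak overlapped the promoter window of any of its transcripts, and 14556 of 21826 genes (66.7%, exact 95% interval 66.1 to 67.3) were marked. The replicates' own lists gave 67.1% and 66.8%, a mean of 67.0% ± 0.237 (SD, n = 2). Of the genes, 14509 were marked in both replicates, 145 in replicate 1 alone and 72 in replicate 2 alone. The share depended on the CpG content of the promoter. When genes were ranked by the number of CpG dinucleotides within 500 bp of a start site and divided into 10 groups of equal size, 0.458% of the genes with the fewest CpGs were marked, 17.2% of the third group, 55.7% of the fourth, 93.7% of the fifth and 99.9% of the group with the most. For this reason presence and breadth in each gene list tested below were also set against genes of the same CpG content. This comparison, like the lists and their tests, was set before the data were examined.

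Genes that pattern the limb carried H3K4me3 without exception. All 38 limb patterning transcription factors were marked, among them Tbx5 of the forelimb, Tbx4 and Pitx1 of the hindlimb, Hand2 and Gli3 of the anterior-posterior axis, and Lmx1b and En1 of the dorsal-ventral axis. All 33 limb signalling genes were marked too, including Shh, Grem1, Fgf8, Fgf10 and Wnt7a. Among all other protein-coding genes 66.6% were marked, and the difference passed Fisher's exact test for both lists (adjusted p = 2.18e-06 and 1.09e-05, two-sided). The calls ended against genes of the same CpG content, among which 36.5 of 38 and 31.7 of 33 were expected to be marked (exact test, adjusted p = 0.589 for each). With nearly all matched genes expected to be marked, even fully marked lists could show no excess in this test.

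Lists of the limb's skeletal and connective tissue lineages followed, none of which was tested against another. Of 22 chondrogenic genes 21 were marked, including Sox9, which directs cartilage formation, and Sox6 and Trps1, whereas Snorc had a peak in replicate 1 only (Fisher's exact test, adjusted p = 0.00495; against genes of the same CpG content the exact adjusted p was 0.0501 and the call ended). Of 13 osteogenic genes 7 were marked. Runx2, the factor that starts bone formation, and Col1a1 were among them, while Bglap and Dmp1, which mature bone cells express, had no peak in any list of a replicate (exact adjusted p = 0.414). All 10 joint interzone genes, Gdf5 and Nog among them, and all 10 genes of the interdigital mesenchyme, such as Aldh1a2 and Rarb of retinoic acid signalling, were marked (exact adjusted p = 0.0554 for each). Of 14 tendon genes 12 were marked, including Scx and Mkx, and Kera and Tnmd were not. The tendon list missed the threshold against all genes (exact adjusted p = 0.186) and passed it against genes of the same CpG content, of which 8.25 were expected to be marked (exact adjusted p = 0.00217). All 9 posterior HoxA and HoxD genes and all 7 posterior HoxB and HoxC genes were marked, which did not pass the test (exact adjusted p = 0.0554 and 0.125). Even with every member marked, the exact p of the HoxB and HoxC list before adjustment was 0.104. A list of 7 could thus not have been called more often marked.

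Other cell types known to lie in the limb include muscle, ectoderm, endothelium, blood and nerve sheath. Of 26 skeletal muscle genes 22 were marked, including Six1, Lbx1 and Myod1. This missed the threshold against all genes (exact adjusted p = 0.0763) and passed it against the 16.1 expected from CpG content (exact adjusted p = 0.00704). With either replicate's own list in place of the replicated one, 88.5% of the muscle genes were marked and the list passed (exact adjusted p = 0.0351 without replicate 2 and 0.0347 without replicate 1). Chrna1 and Chrnd, subunits of the acetylcholine receptor of muscle, had a peak in replicate 2 only. All 19 surface ectoderm genes were marked, Tfap2a and Dlx5 with the broadest domains (exact adjusted p = 0.00199, and 0.0347 against genes of the same CpG content). Of 19 endothelial genes 17 were marked, including Fli1 and Esam but not Emcn and Lyve1 (exact adjusted p = 0.0668, and 0.0238 against genes of the same CpG content). Blood cell lists were marked less often than other genes. Of 19 erythroid genes 5 were marked, namely Tal1, Epor, Klf1, Gypa and Nfe2, and Alas2 and Epb42 of haem synthesis and the red cell membrane were not (exact adjusted p = 0.001). Of 18 macrophage genes only Cd14 was marked in the replicated list, and Adgre1 and Aif1 had a peak in replicate 1 only (exact adjusted p = 1.12e-06). Without replicate 2 the macrophage share was 22.2% and stayed below other genes (exact adjusted p = 0.000363). Both calls ended against genes of the same CpG content, with 4.14 erythroid and 3.27 macrophage genes expected to be marked (exact adjusted p = 0.643 and 0.451), and the erythroid list then lay above the number expected. Of 14 Schwann cell and melanoblast genes 9 were marked, including Erbb3 and Ngfr but not Cdh19 and Dct (exact adjusted p = 0.785).

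Among lists of tissues outside the limb, 2 were marked more often, 3 less often and 2 neither. All 16 forebrain transcription factors, such as Otx1 and Eomes, were marked (exact adjusted p = 0.00495), and so were 18 of 19 neuronal genes, among them Isl2 and Pou4f1, with Phox2b the exception (exact adjusted p = 0.0122). Both calls ended against genes of the same CpG content (exact adjusted p = 0.687 and 0.593). With 15.3 of the 16 forebrain genes expected to be marked, the matched test could show no excess for that list. The forebrain call also ended when the 5′ end of each gene was the single start site used, with 87.5% marked (exact adjusted p = 0.0876). Marked forebrain genes had a median fold enrichment of 13.1, against 51.0 for the limb patterning factors and 67.9 for housekeeping genes in the same list of peaks. Low values were not particular to lists of other tissues. The medians were 9.16 for marked skeletal muscle genes and 12.1 for endothelial genes, and 47.4 for the marked liver genes. Of 21 liver genes 4 were marked, namely Foxa3, Apoh, Apoa1 and Proc, and the domains of Foxa3 and Apoh also reached a promoter of their neighbours Sympk and Prkca. Afp and Ahsg were not marked (exact adjusted p = 4.02e-05, and 0.165 against genes of the same CpG content, which ended the call). With start site windows of 500 bp the liver share was 9.52%. Of 21 germline and pluripotency genes 3 were marked, Dazl, Dppa3 and Tdrd1, and Bmp15 and Ddx4 were not (exact adjusted p = 6.45e-06). The germline list stayed below the 13.3 genes expected from CpG content (exact adjusted p = 5.96e-10). Of 1461 olfactory and vomeronasal receptor genes 3 were marked, Vmn1r4, Olfr94 and Olfr1033, fewer than among other genes with an exact p too small for the software to hold, and 51.0 were expected from CpG content (exact adjusted p = 6.89e-23). Of 16 heart genes 9 were marked, Gata6 and Myl4 but not Mybpc3 and Myh6 (exact adjusted p = 0.447), and of 15 gut and pancreas genes 6, Lgr5 and Nkx6-1 but not Cela1 and Cpa1 (exact adjusted p = 0.0668). Besides the 2 liver genes, 2 forebrain, 1 neuronal, 1 heart and 1 receptor gene that were marked shared a domain with another gene. All 28 housekeeping genes and all 27 cell cycle genes were marked (exact adjusted p = 6.64e-05 and 0.000105), a call that ended against genes of the same CpG content (exact adjusted p = 1 for each).

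**Figure D1:**
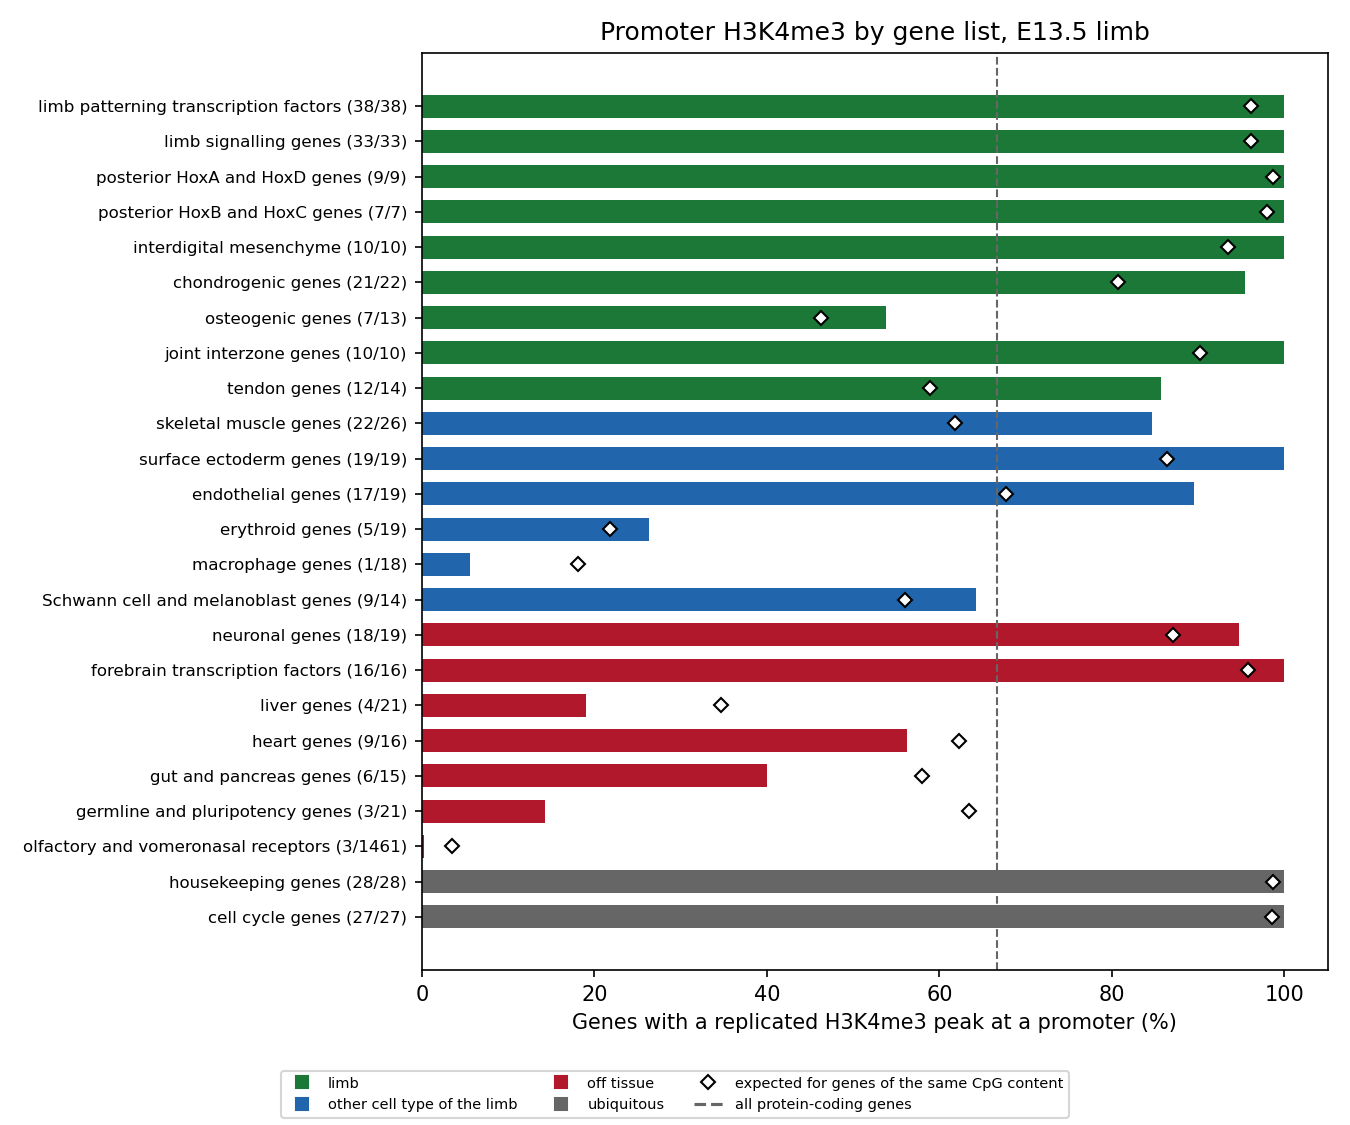
Share of the genes of each list with a replicated H3K4me3 peak at a promoter, in percent on the horizontal axis, with marked and matched genes in brackets. Diamonds give the share expected for genes of the same CpG content and the dashed line the 66.7% of all protein-coding genes, and the germline bar, at 14.3%, lies far to the left of its diamond.

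In all, 8 of the 24 lists were marked more often and 5 less often than other genes, and 4 and 2 lists were so against genes of the same CpG content. That match was coarse where the marked share rose steeply between CpG groups. The fourth group, from 20 to 34 CpGs, held the median counts of the tendon and skeletal muscle lists, 28.5 and 26.5. Differences in CpG content within a group were not accounted for. The limb patterning, limb signalling, forebrain, housekeeping and cell cycle lists were fully marked, as were nearly all of their matched genes. For these the matched test could show no excess, so a call that ended there says little. Genes of a list are not independent replicates, and the tests describe these lists in this tissue. Klf1, Gypa, Nfe2, Apoa1, Proc, Tdrd1 and Olfr1033 are named here to complete short counts and were chosen after their values were seen.

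The broadest promoter domains lay on the HoxA and HoxD clusters. A domain joined the peaks of a replicate that overlapped a replicated peak and lay within 500 bp of each other. Its breadth was averaged over the replicates. Over the 14498 genes with a domain in both replicates the median breadth was 2.30 kb, with quartiles of 1692 and 3061 bp. The broadest domain, of 52.8 ± 0.744 kb (SD, n = 2), covered Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13, and the next, of 37.1 ± 1.04 kb, covered Hoxd9 to Hoxd13. Single genes followed. Ebf3 had 20.5 ± 0.261 kb, Lmx1b 18.3 ± 0.127 kb (chromosome 2, 33628753 to 33647277 in the replicated list), Ptch1, the Hedgehog receptor, 17.2 ± 1.41 kb, and Tbx5 16.7 ± 0.110 kb (chromosome 5, 119828675 to 119845550). Nr2f2 had 15.9 ± 0.241 kb, Tbx2 14.8 ± 1.98 kb and Wnt5a 14.6 ± 0.0863 kb. Among the 25 broadest domains, 12 touched a gene of a limb list and 10 a limb patterning or Hox factor, including Irx5 at 13.7 ± 0.207 kb, Pitx1 at 13.4 ± 0.129 kb (chromosome 13, 55824066 to 55837764), Tbx4 at 12.7 ± 0.253 kb, Hand2 at 12.6 ± 0.227 kb and Msx1 at 12.2 ± 0.406 kb.

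The other domains among the 25 lay on genes outside the limb lists. Kdm6b, which removes methyl groups from lysine 27 of histone H3, had 14.0 ± 0.165 kb, and Bahcc1 and Tnrc18 had 14.2 ± 0.0537 and 14.0 ± 0.318 kb. Setd1b, a methyltransferase for lysine 4 of histone H3, had 12.6 ± 2.25 kb, and its replicate 1 domain also covered the promoter of Rhof. The receptor gene Pdgfra had 13.1 ± 0.234 kb, the imprinted growth factor gene Igf2 13 ± 0.316 kb, Prdm16 12.4 ± 0.273 kb and Foxc1 12.1 ± 1.18 kb. Tfap2a, of the surface ectoderm list, had 14.0 ± 5.77 kb and Zfhx4 12.6 ± 5.86 kb, so these were the least certain of the 25. The domain on chromosome 7 from 127014017 to 127028497, of 14.3 ± 0.000707 kb, covered 6 neighbouring genes, Mvp, Pagr1a, Gm42742, Prrt2, Maz and Kif22. Several genes central to limb outgrowth had domains between the quartiles of all genes. Shh had 3.03 ± 0.0269 kb, Grem1 2.69 ± 0.00495 kb, Wnt7a 2.59 ± 0.0686 kb and Fgf8 2.54 ± 0.104 kb, while En1 had 5.98 ± 0.0742 kb and Fgf10 4.76 ± 0.612 kb.

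Of the 9 limb lists 6 had broader promoter domains than random lists of genes, as did both ubiquitous lists. The limb patterning transcription factors had a median of 7.82 kb, 3.40 times that of random lists, and the medians of the replicates differed by an SD of 0.204 kb (n = 2). Gli3 of this list had 7.74 ± 0.332 kb. The limb signalling genes had a median of 4.52 kb (ratio 1.97, SD 0.0820 kb between replicate medians), the chondrogenic genes 4.75 kb (ratio 2.07, SD 0.339 kb), with Sox6 at 11.6 ± 0.130 kb, Trps1 at 9.75 ± 0.137 kb and Sox9 at 7.68 ± 0.0771 kb, and the posterior HoxA and HoxD genes 37.1 kb (ratio 16.1, SD 1.04 kb). For each of these 4 lists the two-sided permutation p was 2e-05, the smallest that 100000 random lists can give, with an adjusted p of 9.2e-05. The 10 joint interzone genes had a median of 4.40 kb (ratio 1.91, SD 0.111 kb, adjusted permutation p = 0.00046), with Osr2 at 10.2 ± 0.00283 kb, Creb5 at 6.90 ± 0.948 kb and Gdf5 at 4.41 ± 0.133 kb. The 7 marked osteogenic genes had 3.89 kb (ratio 1.69, SD 0.0488 kb, adjusted permutation p = 0.0198), with Runx2 at 5.54 ± 0.310 kb and Col1a1 at 5.18 ± 0.765 kb. The osteogenic medians within replicates 1 and 2 were 4129 and 4060 bp, both above 3.89 kb. The 9 HoxA and HoxD genes lay in 2 domains, so their values are not 9 separate measurements, and with peaks joined only where they touched their ratio was 8.27 (adjusted permutation p = 0.000115). With bases covered within 5000 bp of a start site it was 4.16 (adjusted permutation p = 9.6e-05).

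The tendon list, with Mkx at 5.94 ± 0.131 kb and Scx at 5.44 ± 0.0636 kb, had a median of 3.19 kb and did not pass (ratio 1.39, adjusted permutation p = 0.0517), although it passed without replicate 1 (ratio 1.41, adjusted permutation p = 0.0375). Against random lists of the same CpG content it passed as well (ratio 1.64, adjusted permutation p = 0.00705), as it did with peaks of −log10 q of at least 2 (adjusted permutation p = 0.0490) and, chosen after seeing the data, with 1 gene per domain (0.0370) and with single-gene domains (0.0204). The interdigital list, with Bambi at 5.05 ± 0.0834 kb and Adamts9 at 5 ± 0.00424 kb, had 3.06 kb (adjusted permutation p = 0.117), and the posterior HoxB and HoxC genes had 3.36 kb (adjusted permutation p = 0.0926). Both passed against random lists of the same CpG content (ratios 1.42 and 1.54, adjusted permutation p = 0.0447 for each). So did the surface ectoderm genes, with a median of 2.91 kb (adjusted permutation p = 0.0926, and 0.0183 with CpG content matched at a ratio of 1.37). Matched on CpG content, 12 lists in all were broader and 2 narrower. Endothelial genes had 2.20 kb (adjusted permutation p = 0.860), Schwann cell and melanoblast genes 2.35 kb (adjusted permutation p = 0.933) and the 5 marked erythroid genes 1.70 kb (ratio 0.738, adjusted permutation p = 0.306). The erythroid list was narrower when covered bases within 5000 bp of a start site were counted, over 8 genes (ratio 0.497, adjusted permutation p = 0.00667). Cd14, the single marked macrophage gene, had 1.62 ± 0.0445 kb and was not tested. Skeletal muscle genes had a median of 2.36 kb (ratio 1.03, adjusted permutation p = 0.897), spread from Six1 at 8.94 ± 0.133 kb and Lbx1 at 7.29 ± 1.15 kb through Myod1 at 2.38 ± 0.129 kb to narrower domains. With peaks joined only where they touched, the muscle list was narrower than random lists (ratio 0.655, adjusted permutation p = 0.00204), and its ratio was below 1 in each replicate alone (0.886 without replicate 2 and 0.969 without replicate 1). Ratios of lists that were not called also crossed 1, with 1.17 for endothelial genes matched on CpG content and 0.915 for surface ectoderm genes with peaks joined only where they touched.

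Of the 7 off-tissue lists 2 were narrower than random lists, and no call of broader was made unless covered bases were counted. The 9 marked heart genes had a median of 1202.5 bp (ratio 0.524, SD 0.136 kb between replicate medians, adjusted permutation p = 0.00664), although Gata6 had 4.59 ± 0.845 kb. The heart call ended when gaps of up to 1000 bp were joined (ratio 0.660, adjusted permutation p = 0.0529) and when bases covered within 5000 bp of a start site were counted, a measure that 12 heart genes had (ratio 0.823, adjusted permutation p = 0.317). The 3 marked germline genes had 0.473 kb (ratio 0.206, SD 0.168 kb, adjusted permutation p = 0.00431), with Dazl at 0.865 ± 0.0283 kb and Dppa3 at 0.473 ± 0.210 kb. Counted as covered bases, over 5 germline genes, the ratio was 0.363 (adjusted permutation p = 0.00812). Neuronal genes had 2.06 kb (adjusted permutation p = 0.481), with Isl2 at 3.59 ± 0.185 kb and Pou4f1 at 3.18 ± 0.112 kb, and liver genes 2.36 kb (adjusted permutation p = 0.933). The 3 marked receptor genes of the olfactory and vomeronasal list had 1.29 kb (ratio 0.563, adjusted permutation p = 0.136). The list was narrower with covered bases counted, over 7 genes (ratio 0.154, adjusted permutation p = 9.6e-05). Forebrain transcription factors had 2.60 kb (ratio 1.13, SD 0.527 kb, adjusted permutation p = 0.447), with Otx1 at 5.08 ± 0.803 kb and Eomes at 4.31 ± 0.377 kb. With peaks joined only where they touched, this list was narrower than random lists (ratio 0.727, adjusted permutation p = 0.0302), and with covered bases counted it was broader (ratio 1.39, adjusted permutation p = 0.0377). Its ratio was 0.923 without replicate 1 and 1.22 without replicate 2. Gut and pancreas genes had 1.94 kb (ratio 0.840, adjusted permutation p = 0.481), and the replicates differed, with a ratio of 0.568 without replicate 1 (adjusted permutation p = 0.0370) and 1.24 without replicate 2 (adjusted permutation p = 0.371).

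Housekeeping genes had a median of 3.63 kb (ratio 1.58, SD 0.104 kb between replicate medians, permutation p = 2e-05, again the smallest possible, adjusted p = 9.2e-05), with Ubb at 5.61 ± 0.227 kb and Polr2a at 5.35 ± 0.0269 kb. That call ended when peaks were joined only where they touched (ratio 1.19, adjusted permutation p = 0.0807). The housekeeping medians within replicates 1 and 2 were 3303.5 and 3156 bp, both below the median of the genes' mean breadths. The SD is therefore not a spread around 3.63 kb. Cell cycle genes had 3.24 kb (ratio 1.41, SD 0.00354 kb, adjusted permutation p = 0.00263), with the cyclins Ccnd2 at 8.15 ± 0.0813 kb and Ccnd1 at 7.16 ± 0.0594 kb. The cell cycle medians within replicates 1 and 2 were 3318 and 3323 bp, both above 3.24 kb. In all, 8 of the 23 lists tested were broader and 2 narrower than random lists.

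**Figure D2:**
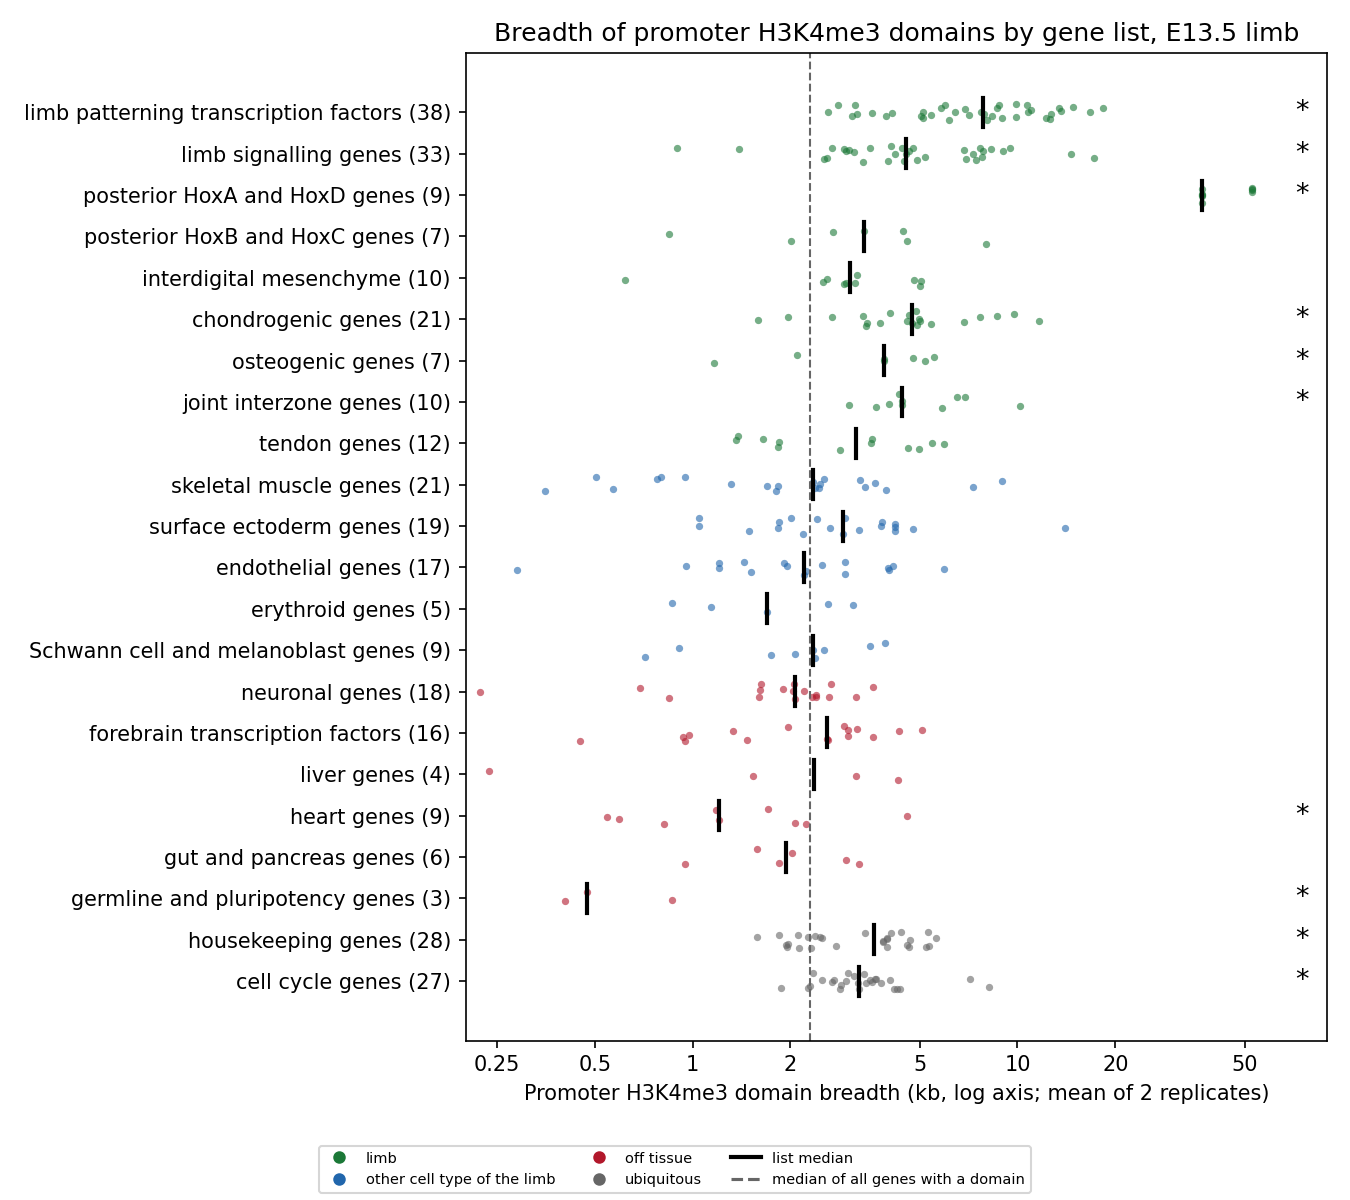
Breadth of the promoter H3K4me3 domain of each gene, in kb on a log axis as the mean of 2 replicates, by gene list with the number of genes in brackets. Black bars are list medians, the dashed line is the median of 2.30 kb over all genes with a domain, asterisks mark adjusted p under 0.05, and the limb patterning factors centre on 7.82 kb.

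The broadest 5% of domains, 726 genes at or above 4.92 kb, were rich in limb genes. They included 30 of 38 limb patterning transcription factors (78.9%), 13 of 33 limb signalling genes (39.4%), all 9 posterior HoxA and HoxD genes, 8 of 21 chondrogenic genes (38.1%) and 4 of 10 joint interzone genes, Osr2, Creb5, Gdf6 and Nog. The adjusted p values of Fisher's exact test, two-sided, were 4.2e-31, 1.94e-08, 2.17e-11, 2.49e-05 and 0.00473. This test was not matched on CpG content. Median breadth rose from 1130 bp in the third CpG group to 3076 bp in the group with the most CpGs. The 9 HoxA and HoxD genes lie in 2 domains, so 2.17e-11 counts each of these domains several times. Among domains that touch a single gene, that list had no member and no test. The 18 other lists tested did not pass. Of these, tendon genes came nearest with 3 of 12 (exact adjusted p = 0.0751), and osteogenic genes had 2 of 7 (0.141), interdigital genes 2 of 10 (0.221), posterior HoxB and HoxC genes 1 of 7, Hoxc10 (0.632), muscle genes 2 of 21, Six1 and Lbx1 (0.632), and cell cycle genes 2 of 27, Ccnd2 and Ccnd1 (0.757). These small counts depended on the replicate, with 1 of 7 osteogenic genes (14.3%) without replicate 1, and 1 of 10 interdigital (10%) and 2 of 7 HoxB and HoxC genes (28.6%) without replicate 2. Surface ectoderm, endothelial and forebrain lists had 1 gene each, Tfap2a, Fli1 and Otx1, and the erythroid, Schwann cell and melanoblast, neuronal, liver, heart, gut and pancreas, germline, and olfactory and vomeronasal lists had none. Without replicate 2 the surface ectoderm list had 3 of 19 (15.8%) and the forebrain list none, and without replicate 1 the heart list had 1 of 9 (11.1%). Housekeeping genes had 4 of 28 (exact adjusted p = 0.141) and passed without replicate 2, with 17.9% (exact adjusted p = 0.0448), and with gaps of up to 1000 bp joined, with 25% (exact adjusted p = 0.00137). Among domains that touch a single gene, an analysis chosen after seeing the data, the interdigital share was 33.3% (exact adjusted p = 0.0278) and the osteogenic share 42.9% (exact adjusted p = 0.015), and both passed. With peaks joined only where they touched, the osteogenic, tendon and interdigital lists passed (exact adjusted p = 0.0123, 0.00852 and 0.033). Among the broadest 10% the same 5 lists passed, and housekeeping genes too, with 32.1% against 9.96% of other genes (exact adjusted p = 0.00444).

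The posterior HoxA and HoxD genes, which direct outgrowth and digit formation in the limb, lay in domains far broader than their HoxB and HoxC counterparts. Their mean breadth was 44.0 ± 8.27 kb (SD over 9 genes) against 3.71 ± 2.31 kb (SD over 7 genes), a ratio of 11.9. The 9 genes lie in 2 domains, so 8.27 kb is not a spread over 9 measurements. Taken as 2 domains, the mean was 44.9 ± 11.1 kb (SD, n = 2). The narrowest HoxA or HoxD value, 37.1 kb, exceeded the broadest HoxB or HoxC value, 8.03 kb at Hoxc10. The median fold enrichment at their promoters was 61.8 and 10.8. The HoxA domain spanned chromosome 6 from 52215202 to 52268622 in the replicated list, across the exons, introns and intergenic stretches of Hoxa7 to Hoxa13 and the noncoding genes Hoxa11os and Hottip. Peaks covered 99.0% of the domain as drawn in replicate 1 and 97.8% of that drawn in replicate 2, and the widest replicated peak within it was 39.1 kb. The HoxD domain spanned chromosome 2 from 74663114 to 74701162 in the replicated list, and peaks covered 99.2% and 97% of the domains drawn in replicates 1 and 2. The remaining genes of these clusters had shorter domains, of at most 9.19 kb, several of them still broader than the median of all genes. Hoxa3 and Hoxa6 had 9.19 ± 3.79 kb, Hoxa5 8.33 ± 5.01 kb, Hoxa1 4.87 ± 0.0495 kb, Hoxa2 3.21 ± 0.242 kb, Hoxa4 2.43 ± 0.00636 kb, Hoxd3 4.73 ± 0.858 kb, Hoxd8 4.07 ± 0.115 kb, Hoxd1 1.82 ± 0.0955 kb and Hoxd4 0.899 ± 0.0622 kb. In HoxB and HoxC, Hoxc12 had 4.56 ± 1.63 kb, Hoxc11 4.44 ± 0.0177 kb, Hoxc9 3358 ± 850 bp, Hoxc13 2.71 ± 0.169 kb, Hoxb9 2.00 ± 0.0544 kb and Hoxb13 0.846 ± 0.0474 kb. Of all 39 Hox genes 38 were marked, and Hoxb3 had a peak in replicate 2 only.

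The difference between the HoxA and HoxD genes and the HoxB and HoxC genes had a two-sided exact permutation p of 0.000175 over genes, the smallest this design allows. With 1 gene per domain, an analysis chosen after seeing the data, 2 domains stood against 7 at a ratio of 12.1, and the exact p was 0.0556, also the smallest possible, so that this comparison cannot pass 0.05. The ratio was 6.99 with peaks joined only where they touched, and 2.43 when covered bases within 5000 bp of a start site were counted, a measure that a long domain fills (exact p = 0.000175 for both).

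**Figure D3:**
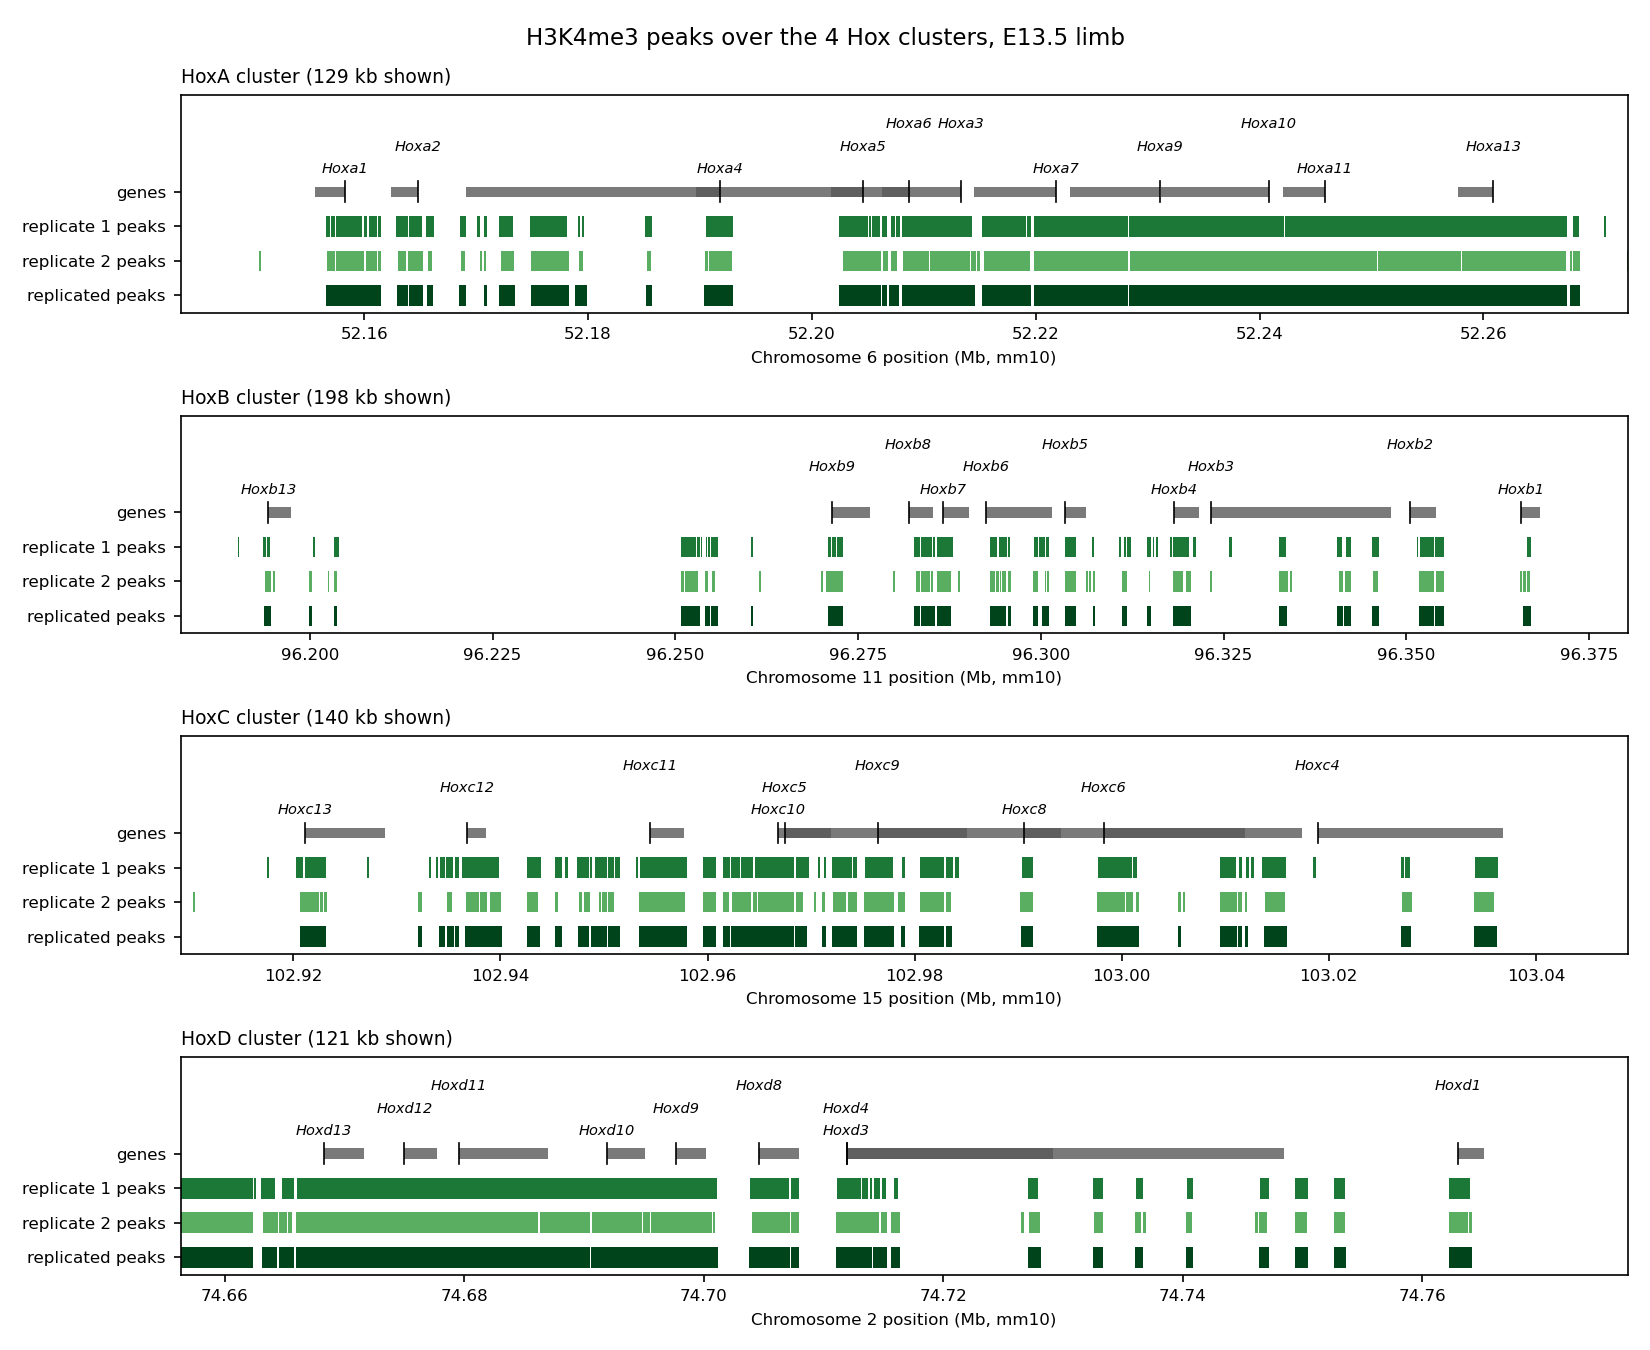
H3K4me3 peaks of replicate 1, replicate 2 and the replicated list along the 4 Hox clusters, with genes in grey, start sites as ticks and mm10 positions in Mb on the horizontal axis. Peaks cover the posterior part of HoxA and HoxD almost without a gap, and are separate at HoxB and HoxC.

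Promoter domains were nearly alike in the replicates, with a small number of genes that differed. Across the 14498 genes with a domain in both, the rank correlation of breadth was 0.962 (Spearman's rho, across genes, which are not independent replicates) and the median ratio of replicate 1 to replicate 2 was 1.02. The median SD of a gene's breadth was 96.2 bp, a coefficient of variation of 4.34%, and 97.4% of genes lay within 1.5-fold. The domains of 130 genes differed more than 2-fold. Of these, 84 had a domain of at least 1000 bp in a replicate. Among genes with such a domain, the largest ratios of replicate 1 to replicate 2 belonged to Dbx1 (21.7), Dqx1 (19.1), Tymp (11.8), Fbxl22 (10.7) and Rhof (7.27), and the smallest to Igflr1 (0.0725), Hfe2 (0.132), Samd10 (0.279), Chmp2a (0.308) and Plvap (0.317). The domain of Dbx1 measured 4403 bp in replicate 1 and 203 bp in replicate 2, and that of Igflr1 232 and 3199 bp.

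**Figure D4:**
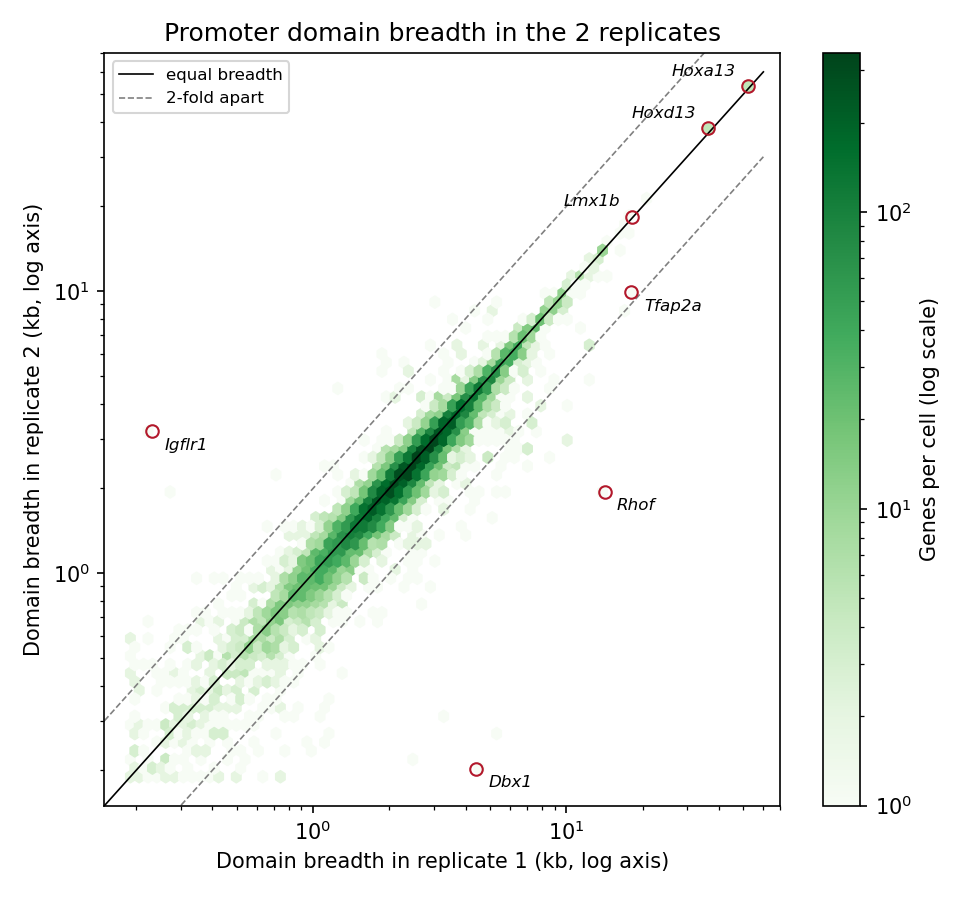
Breadth of each gene's promoter H3K4me3 domain in replicate 1 (horizontal) against replicate 2 (vertical), in kb on log axes, with colour for the number of genes per cell and circles for named genes. Most genes lie on the line of equal breadth, with a rank correlation of 0.962, and Dbx1, Rhof and Igflr1 lie beyond the dashed lines that mark a 2-fold difference.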

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

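Peaks outside the main chromosomes were used in no comparison. The replicated list held 11 such peaks on 6 unplaced or unlocalised contigs, covering 10529 bp, with fold enrichments from 3.19 to 43.4. They stood out because a signal was present in sequence no comparison used. No explanation was tested for them.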

How the results depend on the processing

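Gene 5′ ends as single start sites lowered the share of replicated peaks at promoters to 50.1% and of marked genes to 63.7%. Windows of 500 bp gave 56.2% and 66.2%, and windows of 2000 bp 62.8% and 67.4%. The pooled list gave 67.4% marked genes, and leaving out a replicate 66.8% to 67.1%. Overlap averaged over both directions was 83.5%, and 72.0% at a reciprocal 50%, where the rank correlation of fold was 0.960. Peaks with −log10 q of at least 2 gave a rank correlation of 0.894, 81.5% of pooled peaks kept and a rank correlation of breadth of 0.958. With a gap of 0 bp the latter was 0.944 and the median ratio 1.03. These alternatives change which peaks or start sites enter, or how peaks are matched or joined. Against genes of the same CpG content, 4 lists were marked more often and 2 less often, and the erythroid list, at 26.3%, turned from below to above its background without passing, as did the osteogenic list at 53.8% and the Schwann cell and melanoblast list at 64.3%. The latter also turned with gene 5′ ends (64.3%) and without replicate 1, with leave-one-out values of 64.3% to 71.4%. Windows of 500 bp added calls of more often marked for the posterior HoxA and HoxD, joint interzone, interdigital and endothelial lists, 12 in all. With a gap of 0 bp, 4 lists were narrower, among them muscle (ratio 0.655) and forebrain (ratio 0.727), whose ratios had been above 1, and 8 were enriched in the broadest 5%. Ratios of lists not called turned too, at 0.915 for surface ectoderm and 1.02 for endothelial genes with a gap of 0 bp, at 1.17 for endothelial genes matched on CpG content, and with covered bases at 0.893 for muscle (23 genes in place of 21), 1.05 for endothelial and 0.824 for liver genes (6 in place of 4). Domains with a single gene gave 1.02 for endothelial genes. Leaving out a replicate gave 0.886 to 0.969 for muscle, 0.923 to 1.22 for forebrain and 0.568 to 1.24 for gut and pancreas genes. With a gap of 1000 bp 1 list was narrower. The interdigital list was called broader with gaps of 0 and 1000 bp, with covered bases and matched on CpG content. The HoxB and HoxC list was called broader in the last 3 of these, and the surface ectoderm list with a gap of 1000 bp, matched on CpG content and with single-gene domains. Shares in the broadest 5% crossed those of other genes with a gap of 0 bp for muscle (4.76%), housekeeping (3.57%) and forebrain genes (0%), and with a gap of 1000 bp for neuronal genes (5.56%). In the broadest 10% muscle (9.52%), liver (25%) and heart genes (11.1%) crossed. Leaving out a replicate gave 0% to 6.25% for forebrain and 0% to 11.1% for heart genes. The cause of these changes was not tested. Chosen after seeing the data, 1 gene per domain left the Hox ratio at 12.1 but 2 domains too few to pass. It also left 1 cell type list with an unusual breadth ratio between replicates in place of 2. With 1 gene per domain the HoxA and HoxD list, and with single-gene domains too, had fewer than 3 domains and no list test. Of 203 breadth results by list under an alternative, 168 kept their direction and side of the threshold, as did 166 of 192 for presence and 141 of 158 for the broadest 5%. The unknown depth limits what the absence of a peak can show.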

Other observations

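Some of the widest H3K4me3 peaks away from protein-coding promoters lay on noncoding genes. Of 10878 replicated peaks away from protein-coding promoters, 526 were at least 2000 bp wide and 19 at least 5000 bp. The widest lay on Malat1, a nuclear noncoding RNA gene, with 8.82 kb on chromosome 19 (5795812 to 5804634), and the neighbouring Neat1 had 6.13 kb. Promoters of microRNA host transcripts were among them, with 6.72 kb at the host of Mir125b-1, 6.44 kb on chromosome X at the cluster of Mir322, Mir503 and Mir351, and 5.23 kb at Dnm3os, the host of Mir199a-2. Some wide peaks lay near limb factors but away from their start sites, with 5.60 kb between genes at 31.2 kb from Tbx5 and 4.74 kb at the long noncoding gene 9430024E24Rik at 74.0 kb from Lmx1b. These features were singled out after their values were seen.

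Of 5854 annotated long intergenic noncoding genes 934 (16%) had a replicated peak at a start site, 561 of them through a peak away from any protein-coding promoter. Of 2959 antisense genes 1065 (36.0%) did, 213 of them away from such promoters. Replicated peaks were densest on chromosome 11, at 16.7 per Mb, and sparsest on X, at 4.50 per Mb, among chromosomes other than Y, which had 6 peaks.

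The patterns below were noticed in these data, and the tests were set down before their results were seen, except the comparison with 1 gene per domain, which was chosen afterwards. The design gives no groups, and no biological explanation was tested against the technical ones.

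All 16 forebrain transcription factors were marked in limb. CpG content is a candidate explanation, since 15.3 of 16 genes of the same content were expected to be marked. The exact p of the matched test was 0.544. With all 16 genes marked, this p could not have gone against CpG content at that expected number. Cells of neural tissue in the dissection could also give such peaks, at a low fold enrichment in proportion to their share. The list's median fold was 19.4% of the housekeeping median (bootstrap 95% interval 10.5 to 32.0), above the limit of 10% set in favour of such cells, while the interval reaches below the 25% set against them, so this stays open.

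A larger share of pooled peaks was kept in the replicated list on chromosome X, 90.2% against 76.2% on autosomes. Fewer weak peaks on X may account for it, since 10.3% of X peaks and 25.7% of autosomal peaks lay in the lowest of 4 groups ranked by fold, and with the 4 groups weighted alike the difference of 14.0 percentage points fell to 1.30 (bootstrap 95% interval -0.935 to 3.49). Of the lowest group 18.2% were kept on X and 17.3% on autosomes, of the second 93.9% and 89.6%, and of the upper 2 groups 100% on both, so only the lower 2 can differ. Strong promoter peaks were also lower on X, with a 90th percentile of fold of 45.1 against 71.8, a ratio of 0.629 (interval 0.609 to 0.655). Fewer active X copies in tissue of both sexes would lower the fold of X peaks in this way. Whether weak X peaks then fell below the calling limit was not tested, and the single X of males was not separated from X inactivation.

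The domains of 84 genes with at least 1000 bp in a replicate differed more than 2-fold, 67 broader in replicate 1 and 17 in replicate 2. Some of these genes share a domain with a neighbour. The counts, and the intervals drawn over genes, therefore do not rest on 84 separate domains. Joining in one replicate and splitting in the other may account for most of this, as the bases covered within 5000 bp of the start site differed by a median absolute log2 ratio of 0.21 (bootstrap 95% interval 0.18 to 0.25), although that window does not see the outer parts of long domains. With −log10 q of at least 2 the median absolute log2 ratio of breadth was 1.23 (interval 1.17 to 1.32), against 1.31 with all peaks. Peaks below that limit therefore contributed little to the ratios as measured. Domains held only peaks that overlapped a replicated peak, so many weak peaks had been left out before this test. It can say little about weak peaks in general. In the full lists, rather than in these domains, peaks without an overlap in the other replicate fell only from 6579 to 4457 in replicate 1. In replicate 2 they fell from 4026 to 3330. Weak peaks above the limit, called in 1 replicate, therefore stay open.

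A further hypothesis was that the dissections held different shares of cell types, which would shift the breadths of cell type lists between replicates. Of 14 lists, 2 had a median ratio outside the central 95% of random lists, the posterior HoxA and HoxD genes with a ratio of replicate 1 to replicate 2 of 0.961 and the erythroid genes with 0.909. The 9 HoxA and HoxD genes lie in 2 domains, too few to be set against random lists of 9 separate genes. With 1 gene per domain, 1 of 13 lists lay outside, the erythroid genes. At least 4 had been set as the number that would favour the hypothesis and at most 2 as the number against it, so no shift of breadth across many lists was seen. How far breadth follows the share of a cell type was not measured. Different shares, or a difference in blood cells alone, therefore stay open.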
